A study of Xenopus laevis with 46 samples.

How the data were processed

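RNA was measured in 46 libraries of Xenopus laevis embryos. Per the labels' protocols, morpholino and mRNAs were injected at the 2-cell to 4-cell stage, LiCl was applied at the 32-cell stage, and half-embryos were dissected at stage 8 and grown to stage 10.5. PolyA+ TruSeq libraries were sequenced as 100-base single-end reads on an Illumina HiSeq, per the labels' protocols. Per the same protocols, 100 pg of siamois mRNA was injected marginally, and the Cerberus mRNA is called xCer L, where the meaning of L is not given in the sources used here. The labels name the control library of the same batch for each treated library. For Wnt8 and Cer of replicate 1 at stage 10.5 one field of the labels names stage 10, and these libraries were kept at stage 10.5 as the other fields and the column headings give.

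The deposited values are RPKM that the authors made from the reads, per the file headers, in 1 table for each stage and 1 table of the authors' signature genes. TopHat2 2.09 and DESeq are named in the submitters' processing notes with no stated role. Genome build, annotation version, counting tool and use of strand are not given in the sources used here, and gene identifiers are headed JGI9 per the file headers. Gene names are those the tables pair with the identifiers, and "match" marks a name taken from the best match in a row's description. The separate table of RefSeq names was not used here.

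There were 43662 rows with an identifier at stage 10.5 and 37005 at stage 9. At stage 10.5, 10 rows that repeated an identifier, all at 0, were dropped. Each table also held 1 emptied row and 1 column of the authors' averages, which were not used. Rows at 0 in every library numbered 4355 at stage 10.5 and 0 at stage 9. Every gene of the signature table was found in the full table with the same values, to 0.000001. The stage 10.5 LiCl column numbered 3 was assigned to LiCl replicate 2, because that sample's label names control 3 as its batch and the other LiCl sample is named by its own column.

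Whole reads were recovered from the steps of the RPKM values. Of rows above 0 in at least 5 libraries, 34080 at stage 10.5 and 30836 at stage 9, 100% came out whole within a tolerance of 0.005. Reads in genes ranged from 24.5 M (megareads) to 45.0 M per library at stage 10.5 and from 27.9 M to 58.5 M at stage 9. Between replicates of a group, chi-square per degree of freedom was at least 43.2 at stage 10.5 and 58.74 at stage 9, so no 2 replicates of a group held the same reads. Libraries of different groups were not compared in this way. Floors of 3 reads cover counting error only.

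The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(RPKM + 0.5), which understates the change of low genes. Genes needed 1 RPKM in at least 2 libraries. P-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p below 0.05 with no fold minimum; all tests were two-sided. Whole embryos of a stage were fitted together with group and labelled batch as terms, which left 8 residual degrees of freedom at stage 10.5 and 7 at stage 9. The dorsal and ventral half-embryos had a fit of their own, 5 against 5, with no block. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

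The comparisons were dorsal against ventral half-embryos, each treatment against controls at each stage, and LiCl against Sia. Whether an effect differed between stages was tested over 546 listed genes, from the difference of the log2 fold changes over its standard error with Satterthwaite degrees of freedom. Overlap between bCatMO and LiCl calls was set beside the overlap of independent lists and beside unchanged groups simulated against the same controls. Genes called with an absolute log2 fold change of at least 1 between the half-embryos made the dorsal and ventral sets.

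There were 18 gene lists, holding 458 symbols, of which 389 had a row at stage 10.5 and 351 at stage 9. They were organizer genes, early β-catenin targets, zygotic Wnt targets, Nodal pathway and mesendoderm genes, Wnt, BMP and Nodal antagonists, ventral BMP synexpression genes, and pan-mesoderm and ventrolateral mesoderm genes. Further lists held endoderm, neural plate, epidermis and non-neural ectoderm, ciliated cell and early neuronal genes, and germ plasm and vegetal maternal RNAs. The rest were heat shock and unfolded protein, innate immune and interferon, p53 and DNA damage, mitotic cell cycle, ribosomal protein and reference genes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other genes, and again with an estimated correlation. Of 234 list tests 124 passed with the preset correlation and 30 with the estimated one.

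Symbols were matched to rows at both stages through the names in the stage 10.5 table, because the authors' short names occur only in its descriptions. This matching was chosen after stage 9 list results had been seen under the earlier one, which used each table's own descriptions. It gave 18 rows in place of 2 for early β-catenin targets at stage 9, 56 in place of 67 for the Nodal list, 42 in place of 40 for endoderm and 54 in place of 52 for organizer genes.

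Genes named in the text were chosen by a rule set before the data were examined, as were the tests, the lists and most of the other settings tried. The rule takes the genes a treatment targets or supplies (ctnnb1, siamois, wnt8a, cer1), called or not. Among called genes with a symbol that moved the same way in every batch, or whose half-embryo groups did not overlap, and with a mean of at least 5 RPKM in the higher group, it takes the 4 largest rises and the 4 largest falls. From each list it takes the 2 called members with the smallest adjusted p. Not every gene the rule allows is printed, and a gene named outside it is said to be chosen after its values were seen.

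Same-numbered dorsal and ventral libraries deviated together from their group means, with correlations of 0.92, 0.87, 0.91, 0.46 and 0.84. Each library correlated best with its own number, the highest correlation with another number being 0.15. The pairing of the half-embryos thus comes from the data, while the pairing of treated and control whole embryos comes from the labels, where correlations ranged from 0.75 to 0.93. The block of the pair is given beside the half-embryo results in the text whose call it changes or whose count it moves by over 1.5 times.

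The fit was tested on simulated data in which 100 genes changed by 2-fold and 100 by 4-fold. At stage 10.5, it recovered 86% and 95% for bCatMO (16 unchanged genes called, 17956 genes), 81% and 97% for LiCl (12, 17957 genes) and 91% and 98% for Wnt8 (9, 17959 genes). At stage 9, it recovered 83% and 98% for bCatMO (14, 17798 genes) and 93% and 98% for Wnt8 (15, 17761 genes). For the half-embryos it recovered 98% of each (11, 17530 genes). The simulated half-embryo libraries held no difference between pairs, unlike the real ones, so these shares may not hold for the real data. The spread between replicates was assumed in all simulations.

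The other settings chosen at that point were pseudocounts of 0.1 and 1, no filter, median-of-ratios size factors, homeologs summed, no batch term (or, for the half-embryos, the replicate block), the libraries of a comparison alone, a log2 fold minimum of 1, and leaving out each library in turn. Chosen after seeing the data were limma's voom on the recovered reads, leaving out batch 4 or pair 4, and the replicate block with voom. So were early β-catenin targets without the siamois row Xelaev18019203m, and the shared list names of the stage 9 list tests.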

Results

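PolyA-selected RNA of Xenopus laevis embryos, a frog whose Spemann organizer on the dorsal side directs the body axis, was sequenced at 2 stages. There were 29 libraries at stage 10.5 (early gastrula) and 17 at stage 9 (late blastula). At stage 10.5 there were 6 libraries of whole control embryos (controls), 3 of embryos injected with a morpholino against β-catenin (bCatMO) and 2 of embryos treated with lithium chloride (LiCl), which stabilises β-catenin. Another 2 were injected with siamois mRNA (Sia), 3 were labelled as injected with xWnt8 mRNA (Wnt8), and 3 were injected with xCer L mRNA (Cer). Dorsal and ventral half-embryos had 5 libraries each. At stage 9 there were 5 control, 2 bCatMO, 2 LiCl, 2 Sia, 3 Wnt8 and 3 Cer libraries. Values are the authors' RPKM. Reads in genes, recovered from those values, had medians of 35.2 M per library at stage 10.5 and 38.5 M at stage 9. The ventral half-embryos held the fewest at stage 10.5, from 24.5 M to 33.8 M, against 26.2 M to 43.5 M for the dorsal ones. Fold changes are on the log2(RPKM + 0.5) scale with the standard error of limma's moderated fit, and means are RPKM ± SD with control means taken over the control libraries of the same batches. Genes called higher or lower passed an adjusted p of 0.05, with no minimum fold. The labels do not state that replicates came from separate clutches of eggs, so p-values measure only the spread between these samples, which may be technical. Rows of near-identical gene copies (nodal3, nodal5, siamois and chordin families, and .L and .S homeologs) can share reads, so a change is less certain for one copy than for the family.

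Dorsal and ventral half-embryos, cut apart at stage 8 and grown to stage 10.5, ask which transcripts lie on the organizer side. Chordin, a secreted BMP antagonist made by the organizer, was among the transcripts with the largest dorsal excess. Its row Xelaev18027421m had 87.2 ± 33.2 RPKM in dorsal and 0.786 ± 0.928 in ventral half-embryos (log2 fold change 6.26 ± 0.38, adjusted p = 3.7e-06, n = 5 per group). The organizer transcription factor goosecoid was higher dorsally in both homeologs (gsc.L 5.46 ± 0.32, adjusted p = 3.4e-06; gsc.S 4.14 ± 0.26, adjusted p = 5.6e-06). So was Xelaev18018866m, a copy of nodal3, a direct target of maternal β-catenin (5.3 ± 0.22, adjusted p = 1.5e-07). The BMP antagonist noggin (nog.L) rose from 0.589 ± 0.251 to 17.6 ± 4.11 RPKM (4.07 ± 0.23, adjusted p = 2.4e-06). Otx2 (Xelaev18041108m), a head transcription factor, rose from 1.15 ± 0.508 to 39.8 ± 9.61 (4.63 ± 0.22, adjusted p = 4.5e-07). On the ventral side, sizzled (szl.L), a BMP-induced inhibitor of Chordin cleavage, had a log2 fold change of -3.93 ± 0.52 (adjusted p = 0.0022). The BMP pseudoreceptor gene bambi.L had one of -2.54 ± 0.26 (adjusted p = 3e-04). Among the 18448 genes tested, 125 were called, 101 higher and 24 lower in dorsal half-embryos. Same-numbered dorsal and ventral libraries deviated together, and with the pair as a block the count was 422 (314 higher).

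By group, 33 of 52 organizer genes were higher dorsally and 0 lower (43 higher adjusted over the list alone, median log2 fold change 2.12, adjusted p = 3.4e-215 by camera). Early β-catenin targets gave 9 of 13 higher (13 adjusted over the list alone, median 2.1, adjusted p = 3.2e-91). Endoderm genes had 9 of 31 higher (19 adjusted over the list alone, median 0.96, adjusted p = 1.5e-76), among them hhex.S at 3.22 ± 0.22 (adjusted p = 7.6e-06). Neural plate genes had 10 of 37 higher (23 higher and 2 lower adjusted over the list alone, median 0.77, adjusted p = 2.9e-53). Of 39 Wnt, BMP and Nodal antagonists, 17 were higher and 4 lower (20 and 5 adjusted over the list alone, median 0.98, adjusted p = 1.3e-40). Nodal pathway and mesendoderm genes had 11 of 51 higher and 1 lower (21 and 3 adjusted over the list alone, median 0.51, adjusted p = 1.4e-45). With an estimated correlation and the pair as a block, the call of the Nodal list was lost (adjusted p = 0.00047 without the block and 0.056 with it). Ventral BMP synexpression genes had 12 of 34 lower dorsally (21 lower and 1 higher adjusted over the list alone, median -0.74, adjusted p = 4.2e-50). Epidermis genes had 10 of 40 lower (20 lower and 1 higher adjusted over the list alone, median -0.92, adjusted p = 1.4e-34), including the KLF2 match Xelaev18006666m at -1.72 ± 0.14 (adjusted p = 3.4e-05). With an estimated correlation these 2 lists had adjusted p = 0.0012 and 0.0034 without the block, and 0.072 and 0.076 with it. Germ plasm RNAs shifted up as a set (median 0.16, adjusted p = 8.4e-07) with 0 of 19 called (1 higher adjusted over the list alone). With an estimated correlation adjusted p was 0.029, and 0.15 with the block. With the pair as a block the counts of genes called rose to 20 higher for endoderm, 25 higher and 3 lower for the Nodal list, 20 lower and 1 higher for each of epidermis and ventral BMP, and 3 higher for germ plasm. Neural plate genes then had 15 higher and 1 lower and antagonists 18 higher and 6 lower, against 40 higher for organizer genes and 11 for early targets.

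Mesoderm genes went both ways between the half-embryos, 2 of 36 higher and 1 lower (8 and 7 adjusted over the list alone, median -0.14 and mean -0.04, with the test pointing up, adjusted p = 0.79). With the pair as a block 9 were higher and 5 lower, and zygotic Wnt targets had 5 higher and 6 lower in place of 0 and 1. The authors' signature genes had 67 higher and 0 lower (112 and 0 adjusted over the list alone, median 1.77, adjusted p = 8.1e-06 with an estimated correlation). With the pair as a block 112 were higher. The authors chose them on these samples, so this is not independent evidence of their direction. Genes called at 2-fold or more made up a dorsal set of 96 and a ventral set of 21, which are followed through the treatments. Leaving out any 1 library gave counts from 90 to 123, and leaving out pair 4, an alternative chosen after seeing the data, gave 70.

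**Figure D1:**
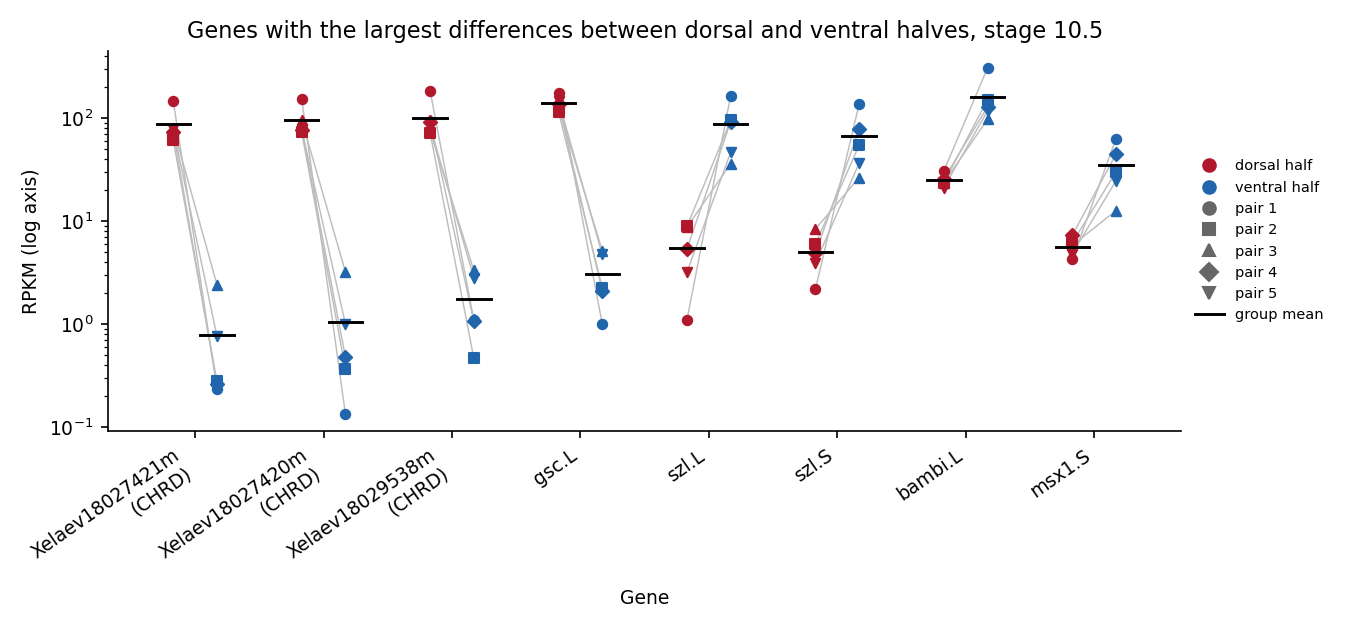
RPKM on a log axis of named genes in the 5 dorsal and 5 ventral half-embryo libraries, 1 point per library with bars for the group means. Chordin (Xelaev18027421m) averaged 87.2 in dorsal and 0.786 in ventral libraries, and szl.L averaged 5.44 and 86.6.

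In the bCatMO libraries at stage 10.5, which ask what depends on β-catenin, ctnnb1 mRNA was measured first. Its row Xelaev18033202m had 335, 314 and 306 RPKM against 346, 321 and 319 in controls of the same batches (-0.05 ± 0.04, adjusted p = 0.54). The second row, Xelaev18031149m (253, 208 and 190 against 369, 298 and 286), was lower in 3 of 3 batches (-0.55 ± 0.04, adjusted p = 7.9e-06). It was also lower in LiCl, at 240 and 229 against 298 and 286, and at stage 9 (214 and 197 against 246 and 224). A morpholino that blocks translation need not change its message, so these values are no check of the labels. Organizer transcripts fell steeply. The secreted antagonist of Nodal, BMP and Wnt cer1.S fell from 88.6 ± 23.0 to 2.00 ± 2.17 RPKM (-5.46 ± 0.39, adjusted p = 5.8e-06, n = 3). Chordin Xelaev18027420m fell from 40.9 ± 5.89 to 0.923 ± 1.28 (-5.22 ± 0.39, adjusted p = 7.5e-06) and nodal3 Xelaev18018866m from 24.9 ± 0.629 to 0.456 ± 0.48 (-4.85 ± 0.22, adjusted p = 2.2e-07). Also lower were nog.L (-3.96 ± 0.12, adjusted p = 1.2e-08), gsc.S (-3.51 ± 0.18, adjusted p = 4.7e-07) and the Wnt antagonist dkk1.S (-3.54 ± 0.21, adjusted p = 1.3e-06). Among genes that the naming rule allows, the largest rises included zfand2a.L, a zinc-finger stress protein gene (2.46 ± 0.10, adjusted p = 6.7e-08), the mitotic kinase gene pbk.L (2.45 ± 0.16, adjusted p = 2.4e-06) and the histone deacetylase gene hdac2.S (1.91 ± 0.10, adjusted p = 6.8e-07). Of 18834 genes tested, 1346 were called, 372 higher and 974 lower, and 131 of them by 2-fold or more.

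Of 52 organizer genes, 35 fell and 0 rose with bCatMO (41 lower and 1 higher adjusted over the list alone, median -1.21, adjusted p = 1.3e-37). Early β-catenin targets fell in 13 of 16 cases (15 adjusted over the list alone, median -1.68, adjusted p = 2.1e-24 and 0.005 with an estimated correlation). The list holds only copies of nodal3, nodal5, nodal6 and siamois genes, so its counts are not of independent genes. Wnt, BMP and Nodal antagonists had 17 of 41 lower and 2 higher (19 and 5 adjusted over the list alone, median -0.35, adjusted p = 4.3e-10). Neural plate genes had 17 of 39 lower and 2 higher (21 and 2 adjusted over the list alone, median -0.40, adjusted p = 3e-09, but adjusted p = 0.11 with an estimated correlation). Otx2 was lower (Xelaev18041108m, -3.82 ± 0.22, adjusted p = 1.3e-06). Endoderm genes had 9 of 33 lower (10 adjusted over the list alone, median -0.38, adjusted p = 4.3e-07, and 0.11 with an estimated correlation). Among them was hhex.S at -2.83 ± 0.18 (adjusted p = 2.2e-06). Zygotic Wnt targets had 9 of 40 lower (14 lower and 1 higher adjusted over the list alone, median -0.22, adjusted p = 1.2e-05, adjusted p = 0.25 with an estimated correlation). Of these, hoxd1.S was at -2.05 ± 0.24 (adjusted p = 0.00029). Nodal pathway genes had 10 of 52 lower and 3 higher (14 and 4 adjusted over the list alone, adjusted p = 0.00037, and 0.58 with an estimated correlation).

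Epidermis genes moved the other way, with 7 of 39 higher and 1 lower (14 and 3 adjusted over the list alone, median 0.25, adjusted p = 1.2e-05, adjusted p = 0.36 with an estimated correlation). So did ventral BMP genes, with 6 of 33 higher and 3 lower (12 and 5 adjusted over the list alone, median 0.24, adjusted p = 0.014, adjusted p = 0.58 with an estimated correlation). Ciliated cell and early neuronal genes had 5 of 12 higher (5 adjusted over the list alone, median 0.26, adjusted p = 0.00078). One was the ELAVL3 match Xelaev18004445m (0.95 ± 0.15, adjusted p = 0.0024). Of the lists that did not pass, mesoderm had 1 of 36 higher and 4 lower (adjusted p = 0.78), cell cycle 4 of 49 higher and 8 lower (adjusted p = 0.44) and ribosomal protein 0 of 144 higher and 4 lower (adjusted p = 0.35). The p53 and DNA damage list had 0 of 27 higher and 3 lower (adjusted p = 0.63), heat shock 1 of 24 higher and 1 lower (adjusted p = 0.12) and innate immune 1 of 16 higher (adjusted p = 0.37). Germ plasm had 1 of 21 higher and 1 lower (adjusted p = 0.6) and reference genes 1 of 33 higher and 2 lower (adjusted p = 0.16). The dorsal set of 96 genes had a median of -1.42, with 79 lower and 0 higher (adjusted p = 3.2e-79), and one of -2.37 with voom on the recovered reads, chosen after seeing the data. The ventral set of 21 had a median of 0.63, with 7 higher (adjusted p = 2.4e-09, adjusted p = 0.085 with an estimated correlation). Of the authors' signature genes 117 fell and 0 rose (all fell when adjusted over the list alone), but they were chosen on these samples and so are not independent evidence. The count fell to 606 without bCatMO 2, 741 without bCatMO 3, 848 without control 2, 490 without control 3 and 885 without control 1. With no batch term 166 genes were called, and with the libraries of this comparison alone 323.

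**Figure D2:**
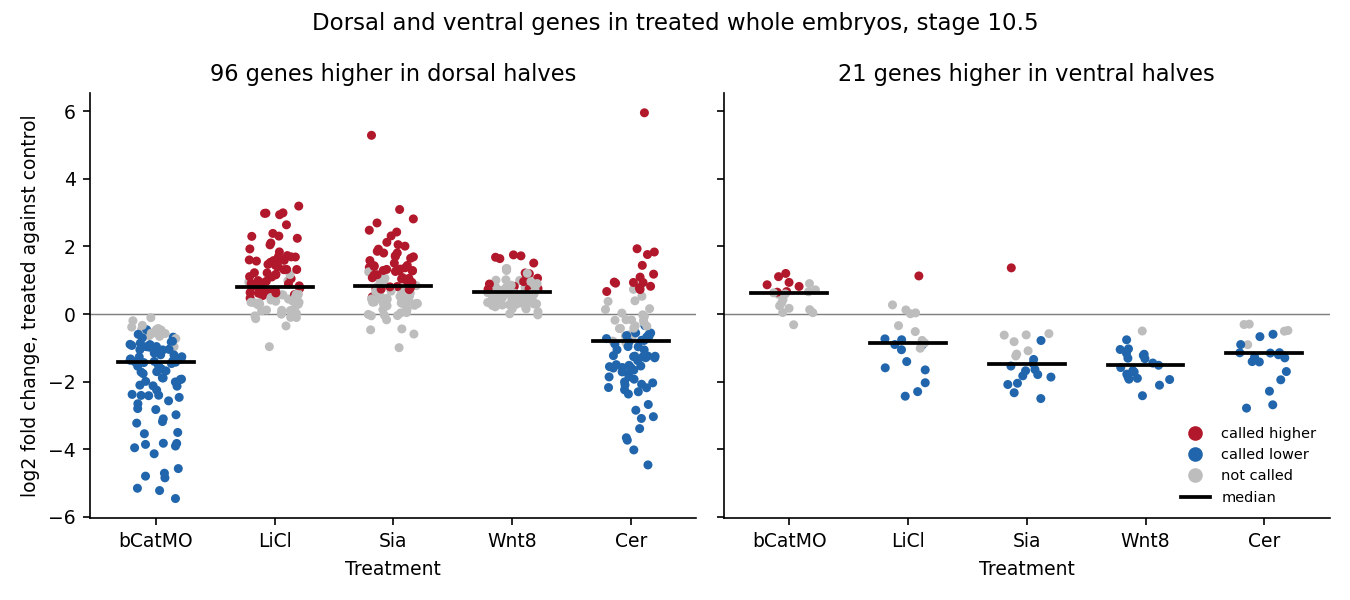
Log2 fold changes against controls at stage 10.5 (vertical axis) of the 96 dorsal and 21 ventral genes in each treatment, 1 point per gene with a line at each median. The dorsal medians were -1.42 (bCatMO), 0.81 (LiCl), 0.83 (Sia), 0.65 (libraries labelled Wnt8) and -0.79 (Cer).

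LiCl, applied at the 32-cell stage, asks what rises when β-catenin is stabilised throughout the embryo. At stage 10.5 the siamois copy Xelaev18000884m, a homeobox target of β-catenin, rose from 0.407 ± 0.217 to 15.1 ± 9.21 RPKM (4.05 ± 0.28, adjusted p = 2.1e-05, n = 2). The zygotic Wnt target hoxd1.S rose from 1.72 ± 0.447 to 28.9 ± 1.45 (3.59 ± 0.28, adjusted p = 4.3e-05). Likewise nog.L rose from 10.5 ± 0.543 to 47.7 ± 2.53 (2.1 ± 0.14, adjusted p = 2.1e-05). The ventrolateral ligand gene wnt8a.S had 6.09 and 0.919 RPKM against 25.8 and 10.2 (-2.43 ± 0.25, adjusted p = 0.00025), and admp2.L, a BMP-family ligand, also fell (-1.88 ± 0.20, adjusted p = 0.00033). The replication factor PCNA (Xelaev18018556m) and mcm6.L, a subunit of the replicative helicase, also fell (-0.71 ± 0.07, adjusted p = 0.00014, and -0.62 ± 0.08, adjusted p = 0.001). In all, 2668 genes were called, 715 higher and 1953 lower, so that 26.8% were higher. After division by median-of-ratios size factors the split turned to 1472 higher and 1341 lower (52.3%).

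Early β-catenin targets had 15 of 16 members higher in LiCl (16 adjusted over the list alone, median 2.06, adjusted p = 5.4e-27). Organizer genes had 24 of 52 higher and 1 lower (26 and 3 adjusted over the list alone, median 0.62, adjusted p = 1e-16). Zygotic Wnt targets had 20 of 40 higher and 3 lower (22 and 4 adjusted over the list alone, median 0.40, adjusted p = 1.1e-12), and neural plate genes had 14 of 39 higher and 2 lower (18 and 4 adjusted over the list alone, median 0.36, adjusted p = 4.8e-08). With an estimated correlation these 3 lists had adjusted p = 0.07, 0.089 and 0.13. Cell cycle genes had 19 of 49 lower and 4 higher (22 and 4 adjusted over the list alone, median -0.17, adjusted p = 0.0018, adjusted p = 0.11 with an estimated correlation). Ribosomal protein genes had 19 of 144 lower (19 adjusted over the list alone, median -0.21, adjusted p = 2.2e-06, adjusted p = 0.61 with an estimated correlation). Among 33 reference genes 6 were lower (median -0.12, adjusted p = 0.11). With size factors these medians kept their sign (-0.09, -0.13 and -0.04). The dorsal set had a median of 0.81, with 57 of 96 higher and 0 lower (adjusted p = 1.2e-41). The ventral set had one of -0.85, with 11 of 21 lower and 1 higher (adjusted p = 1.6e-05, adjusted p = 0.17 with an estimated correlation). Without single libraries the count was 1193 (LiCl 2), 595 (LiCl 1), 1199 (control 3) and 1565 (control 1), each lone library being assumed to vary like the other groups. With no batch term it was 146, of which 78 were higher and 68 lower, and among calls of 2-fold or more 146 were higher and 58 lower.

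Sia libraries, from embryos given 100 pg of siamois mRNA marginally, ask what this homeobox activator can induce. The siamois row Xelaev18019203m rose with the supplied mRNA and had 660 and 638 RPKM against 22.3 and 16.1 in controls (5.29 ± 0.28, adjusted p = 2.1e-07, n = 2). Other siamois rows were not called, such as Xelaev18019205m (0.26 ± 0.30, adjusted p = 0.77). At stage 10.5 nog.L rose from 9.59 ± 0.796 to 53.4 ± 8.35 (2.43 ± 0.14, adjusted p = 5.8e-07). The Wnt receptor gene FZD8 (Xelaev18030716m) rose from 22.7 ± 0.32 to 109 ± 17.7 (2.12 ± 0.18, adjusted p = 1.4e-05), and the neural transcription factor pou3f2.S by 1.94 ± 0.18 (adjusted p = 2.9e-05). The ventral genes wnt8a.L (-3.24 ± 0.27, adjusted p = 1e-05) and the VENTX match Xelaev18034617m (-1.59 ± 0.17, adjusted p = 0.00012), a BMP-induced repressor, fell, as did klf5.S (-1.14 ± 0.09, adjusted p = 1.1e-05), an epidermal transcription factor. Across all genes 784 were called, 440 higher and 344 lower (56.1% higher). The gene with the largest rise was the globin gene hbg1.L, at 50.7 ± 3.39 RPKM (adjusted p = 4e-12). It is listed at 0 in both control libraries of those batches, and the control libraries of the stage together held 1 read of it.

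Organizer genes had 27 of 52 higher and 0 lower in Sia (31 and 2 adjusted over the list alone, median 0.75, adjusted p = 1.4e-21, adjusted p = 0.066 with an estimated correlation). Neural plate genes had 16 of 39 higher and 2 lower (19 and 6 adjusted over the list alone, median 0.32, adjusted p = 5e-08, adjusted p = 0.23 with an estimated correlation). Ventral BMP genes had 14 of 33 lower and 2 higher (23 and 2 adjusted over the list alone, median -0.70, adjusted p = 3.1e-10). Epidermis genes had 15 of 39 lower and 3 higher (22 and 5 adjusted over the list alone, median -0.58, adjusted p = 1.1e-06), and mesoderm genes had 9 of 36 lower and 4 higher (14 and 4 adjusted over the list alone, median -0.46, adjusted p = 0.00043). With an estimated correlation their adjusted p was 0.23, 0.35 and 0.35. Of 16 early β-catenin targets 4 were higher (4 adjusted over the list alone, median 0.13, adjusted p = 0.00082, adjusted p = 0.35 with an estimated correlation). One of the 4 is Xelaev18019203m, the row of the supplied mRNA, and the other 3 are nodal3 copies. Without that row, a test chosen after seeing the data, 3 of 15 were higher (median 0.13, adjusted p = 0.017, adjusted p = 0.49 with an estimated correlation). The dorsal set had a median of 0.83, with 49 of 96 higher and 0 lower (adjusted p = 9.9e-47). The ventral set had one of -1.47, with 13 of 21 lower and 1 higher (adjusted p = 2.9e-19). The count was 359 without Sia 1, 306 without Sia 2 and 454 without control 3. With no batch term 215 were higher and 48 lower (263 in all), with no filter on low values 938 and 299 (1237), and at 2-fold or more 272 and 76.

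In the libraries labelled Wnt8, wnt8a mRNA did not rise at stage 10.5 and was lower than in controls. A fall was not particular to these libraries. In LiCl wnt8a.L had 21.6 and 6.77 RPKM against 74.9 and 43.6, and in Sia 8.03 and 7.51 against 78.7 and 74.9. The labels do not say which part of the gene the injected mRNA holds, so its reads need not count in the wnt8a rows, and these values are a limited check of the label. Of its rows, wnt8a.L had 55.9, 26.4 and 34.7 RPKM against 93.2, 65.7 and 102 in controls (-1.19 ± 0.23, adjusted p = 0.049, n = 3) and wnt8a.S had 6.63 ± 0.734 against 20.9 ± 2.21 (-1.58 ± 0.21, adjusted p = 0.0067). Both calls were lost without Wnt8 2, Wnt8 3, control 4, control 5 or control 6 (adjusted p up to 0.35 and 0.067). In these libraries nog.L rose from 8.25 ± 1.04 to 24.4 ± 3.78 (1.51 ± 0.12, adjusted p = 0.00076). The ventral genes bambi.L (-2.11 ± 0.25, adjusted p = 0.0033) and the VENTX match Xelaev18034617m (-1.72 ± 0.15, adjusted p = 0.00076) fell, as did the KLF2 match Xelaev18001123m (-1.93 ± 0.20, adjusted p = 0.0016) and klf5.S (-0.78 ± 0.08, adjusted p = 0.0016). Nodal3 Xelaev18018866m went from 17.3 ± 0.245 to 58.8 ± 22.0 (1.68 ± 0.22, adjusted p = 0.0063), a call that was lost without control 5. Over all genes 87 were called, 37 higher and 50 lower.

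Ventral BMP genes had 14 of 33 lower in the libraries labelled Wnt8 (23 lower and 1 higher adjusted over the list alone, median -0.68, adjusted p = 1.2e-36). Epidermis genes had 19 of 39 lower (23 lower and 2 higher adjusted over the list alone, median -0.68, adjusted p = 1.5e-25). Organizer genes had 6 of 52 higher (33 adjusted over the list alone, median 0.58, adjusted p = 5.5e-32). Early β-catenin targets had 7 of 16 higher (12 adjusted over the list alone, median 0.79, adjusted p = 9.8e-25) and neural plate genes 2 of 39 (17 higher and 2 lower adjusted over the list alone, median 0.25, adjusted p = 4.4e-14). The dorsal set had a median of 0.65, with 19 of 96 higher (adjusted p = 5.2e-68). The ventral set had one of -1.52, with 20 of 21 lower (adjusted p = 4.5e-61). The count was 28 without Wnt8 2, 25 without Wnt8 3, 27 without control 4, 23 without control 5 and 25 without control 6, and 8 with no batch term. It was 39 with no filter, 57 with homeologs summed and 131 with the libraries of this comparison alone.

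Cer libraries, given mRNA of the secreted antagonist Cerberus, ask what needs the signals it blocks, Nodal among them. Of the cer1 rows, cer1.S rose with the supplied mRNA, to 4600, 4250 and 5760 RPKM at stage 10.5, against 69.5, 59.2 and 112 in controls (5.96 ± 0.39, adjusted p = 2.1e-06, n = 3). Its homeolog cer1.L fell from 17.2 ± 10.5 to 0.237 ± 0.241 (-4.47 ± 0.29, adjusted p = 2e-06), although with homeologs summed cer1 rose by 5.69. The Nodal feedback antagonist lefty.S fell from 22.9 ± 2.90 to 1.26 ± 1.13 (-3.91 ± 0.27, adjusted p = 2.7e-06). The mesoderm transcription factor gene brachyury (t.L) fell from 38.8 ± 19.8 to 3.55 ± 3.75 (-3.61 ± 0.24, adjusted p = 2.5e-06), and hhex.S, an anterior endoderm gene, from 11.7 ± 1.69 to 0.464 ± 0.17 (-3.66 ± 0.18, adjusted p = 2.6e-07). The HES1 match Xelaev18019219m, a transcriptional repressor, rose from 11.5 ± 3.63 to 109 ± 16.0 (3.23 ± 0.25, adjusted p = 7.1e-06). The nodal5 copy Xelaev18018805m rose from 1.22 ± 0.182 to 10.1 ± 1.21 (2.63 ± 0.14, adjusted p = 3.9e-07). Altogether 856 genes were called, 310 higher and 546 lower.

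Of 52 Nodal pathway genes 44 fell and 1 rose with Cer (45 and 1 adjusted over the list alone, median -1.99, adjusted p = 2e-65). Endoderm genes had 24 of 33 lower and 1 higher (25 and 1 adjusted over the list alone, median -1.92, adjusted p = 1.9e-33). Mesoderm genes had 24 of 36 lower (30 adjusted over the list alone, median -1.02, adjusted p = 9.8e-35). Among ventral BMP genes 19 of 33 were lower (24 lower and 1 higher adjusted over the list alone, median -1.01, adjusted p = 2.3e-24), such as the GATA2 match Xelaev18023995m at -2.47 ± 0.21 (adjusted p = 1.2e-05). Organizer genes went both ways, 35 of 52 lower and 8 higher (37 and 10 adjusted over the list alone, median -1.14, adjusted p = 3.3e-23). Zygotic Wnt targets had 18 of 40 lower and 1 higher (22 and 2 adjusted over the list alone, median -0.57, adjusted p = 1.5e-17). Antagonists had 21 of 41 lower and 5 higher (26 and 6 adjusted over the list alone, median -0.83, adjusted p = 4.1e-13). Neural plate genes instead had 20 of 39 higher and 6 lower (22 and 8 adjusted over the list alone, median 0.48, adjusted p = 2.7e-08, adjusted p = 0.093 with an estimated correlation). Among them irx1.S was at 1.28 ± 0.08 (adjusted p = 9.6e-07) but irx3.L at -3.46 ± 0.21 (adjusted p = 1.4e-06). Early β-catenin targets had 8 of 16 higher and 1 lower (8 and 4 adjusted over the list alone, median 0.48, adjusted p = 6e-05, adjusted p = 0.12 with an estimated correlation). Among epidermis genes 16 of 39 were lower and 1 higher (18 and 2 adjusted over the list alone, median -0.45, adjusted p = 5.1e-13, adjusted p = 0.089 with an estimated correlation). The dorsal set, which includes cer1.S itself, had a median of -0.79, with 56 of 96 lower and 15 higher (adjusted p = 1.6e-23). The ventral set had one of -1.16, with 16 of 21 lower (adjusted p = 3e-24). The count was 562 without control 6 and 335 with no batch term.

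**Figure D3:**
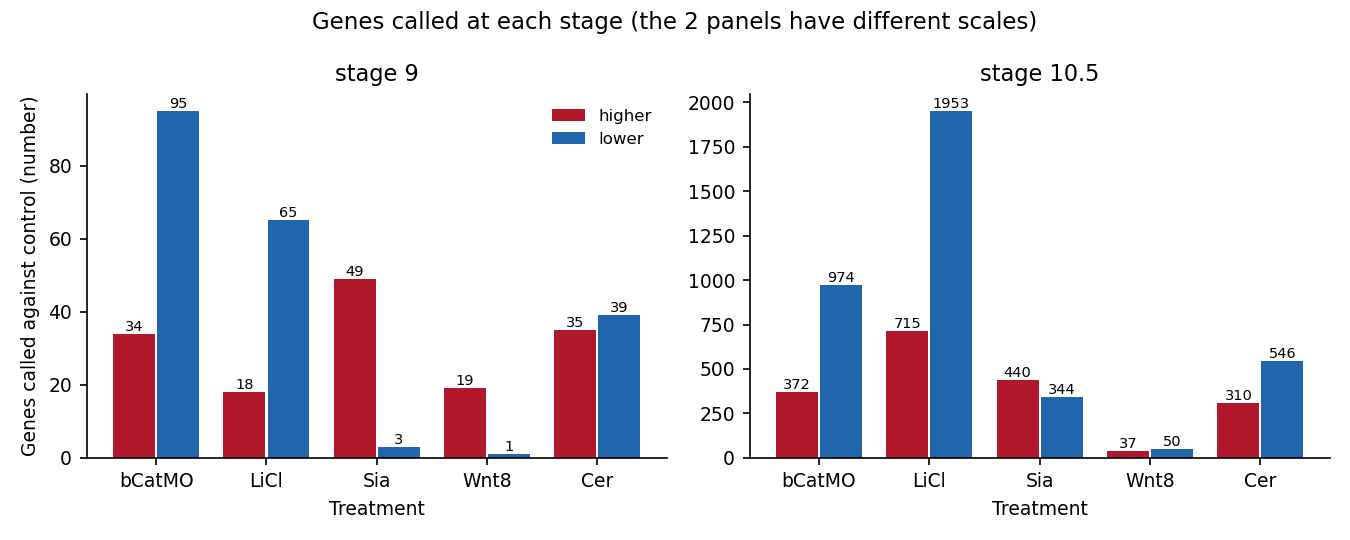
Genes called higher and lower (side-by-side bars) in each treatment against controls at stage 10.5 and stage 9, from limma at an adjusted p of 0.05. The panels of the stages have different scales. LiCl at stage 10.5 had 715 higher and 1953 lower, a split that turned to 1472 and 1341 after division by size factors.

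LiCl set against Sia asks what differs between β-catenin stabilisation and 1 of its targets. At stage 10.5, hoxd1.L had 23.4 ± 1.35 RPKM in LiCl and 0.851 ± 0.269 in Sia (4.12 ± 0.23, adjusted p = 6e-07, n = 2 per group). The myogenic factor myf5.S (2.40 ± 0.25, adjusted p = 0.00014) and nodal1.S, a mesoderm-inducing ligand gene (2.06 ± 0.27, adjusted p = 0.00073), were also higher in LiCl. The neural gene irx2.S (-1.42 ± 0.17, adjusted p = 0.00043) and tbx2.S (-1.98 ± 0.24, adjusted p = 0.00037) were higher in Sia. Early β-catenin targets had 14 of 16 higher and 1 lower in LiCl (14 and 1 adjusted over the list alone, median 1.55, adjusted p = 3.2e-18), the lower one being Xelaev18019203m, the row of the mRNA supplied in Sia. Zygotic Wnt targets had 18 of 40 higher and 1 lower (19 and 2 adjusted over the list alone, median 0.46, adjusted p = 4e-18, adjusted p = 0.068 with an estimated correlation). Mesoderm genes had 12 of 36 higher and 2 lower (18 and 3 adjusted over the list alone, median 0.51, adjusted p = 2.9e-09, adjusted p = 0.19 with an estimated correlation). Organizer genes did not separate the treatments as a set. Of 52, 2 were higher and 4 lower (4 and 10 adjusted over the list alone, adjusted p = 0.92), with a median of -0.01 that was 0.02 under size factors. Ribosomal protein genes had 21 of 144 lower in LiCl (51 adjusted over the list alone, median -0.31, adjusted p = 3.9e-17, adjusted p = 0.55 with an estimated correlation). With size factors 12 were lower and the median was -0.27. In total 1101 genes differed, 277 higher and 824 lower in LiCl, or 25.2% higher, against 37% (381 and 650) with size factors. The count was 404 without Sia 1, 339 without Sia 2, 498 without LiCl 2 and 524 without LiCl 1, 152 with no batch term, and 615 with the libraries of this comparison alone.

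Genes lower in bCatMO and higher in LiCl at stage 10.5 numbered 106, where independent lists would share 37.0. They included chordin (Xelaev18027420m, -5.22 and 2.30), nodal3 (Xelaev18018866m, -4.85 and 2.94), gsc.S (-3.51 and 1.44) and zic1.S (-1.16 and 0.92), a neural plate gene. These examples were chosen after their values were seen. A further 69 were higher in bCatMO and lower in LiCl (38.6 from independent lists), 282 were lower in both (101) and 14 higher in both (14.1). Unchanged groups simulated against the same controls shared 0 genes on average in each of these classes. The simulations left out real effects, so this 0 does not show what shared controls add where such effects exist. With separate control libraries the counts were 20 or 7 for the first class and 0 for the next 2 classes, but then the lists themselves were short, with expected overlaps of 0.3 and 0 for genes lower in both. Those fits also had no batch term, and each set 1 treatment against controls of other batches. Across genes, which are not independent replicates, the log2 fold changes had a covariance of -0.0132 against 0.007 in the simulations (correlation -0.16 and 0.43), and -0.0222 and -0.0108 with separate controls. The count of 106 was 43 without control 3, 58 without control 1, 64 without LiCl 2 and 52 without LiCl 1, 29 with no batch term, 67 with no filter and 44 at 2-fold or more. The 282 lower in both were 5 with no batch term (0.5 from independent lists) and 0 by limma at 2-fold or more (0.3). They were 150 with no filter (22) and 53 with each comparison's own libraries (31.5). Without single libraries they were 99 (bCatMO 2, 41.2 from independent lists), 153 (bCatMO 3, 53.6), 54 (control 3, 17.2), 156 (control 1, 42.3), 162 (LiCl 2, 44) and 80 (LiCl 1, 22.3). The 69 were 0 with no batch term, 3 at 2-fold or more, 33 with no filter and 30 with each comparison's own libraries. They were 19 without control 3, 21 without control 1, 39 without bCatMO 2, 43 without LiCl 2 and 32 without LiCl 1. The 14 were 50 with size factors, 0 with no batch term and 3 with no filter. Without single libraries the 14 ranged from 1 (control 3) to 31 (bCatMO 1).

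At stage 9 the bCatMO libraries had lost early β-catenin targets. The matching of list names at stage 9 was chosen after its list results had been seen. Under the earlier one early targets had 2 rows and were not tested. Ctnnb1 rows were not called (Xelaev18031149m 208 and 194 RPKM against 246 and 224, -0.22 ± 0.07, adjusted p = 0.37). Sia2 (Xelaev18019205m), a siamois-related homeobox gene, had 0.0624 ± 0.0436 RPKM against 18.4 ± 1.83 (-5.07 ± 0.17, adjusted p = 7.3e-08, n = 2). The nodal3 row Xelaev18018867m (-5.21 ± 0.29, adjusted p = 7.3e-06) was also lower. Another gene that fell was admp.S, a BMP-family ligand of the organizer (-3.41 ± 0.32, adjusted p = 2e-04). Pbk.L (3.1 ± 0.18, adjusted p = 7.3e-06), zfand2a.L (1.56 ± 0.12, adjusted p = 4.1e-05) and the mitotic kinase plk1.L (1.19 ± 0.14, adjusted p = 0.0014) rose. Early targets had 13 of 17 lower (16 adjusted over the list alone, median -2.93, adjusted p = 4.1e-71). Organizer genes had 13 of 40 lower (23 lower and 1 higher adjusted over the list alone, median -1.04, adjusted p = 1.2e-29, adjusted p = 0.063 with an estimated correlation). Nodal pathway genes had 8 of 47 lower (21 adjusted over the list alone, median -0.50, adjusted p = 3.4e-21, adjusted p = 0.087 with an estimated correlation). Under the earlier matching they had 15 of 57 lower (median -0.77, adjusted p = 2.4e-37, adjusted p = 0.079 with an estimated correlation). In all 129 of 18530 genes were called, 34 higher and 95 lower. The count was 74 without bCatMO 1, 60 without bCatMO 2, 50 without control 4 and 68 without control 5, 51 with no batch term, 84 with no filter and 407 with the libraries of this comparison alone.

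LiCl at stage 9 gave 83 genes, 18 higher and 65 lower. The siamois copies Xelaev18000884m (35.8 ± 5.97 against 5.14 ± 0.762 RPKM, 2.68 ± 0.21, adjusted p = 0.00076, n = 2) and Xelaev18019204m (2.68 ± 0.23, adjusted p = 0.0014) were higher, the second call being lost without control 4. Early β-catenin targets had 4 of 17 higher (9 adjusted over the list alone, median 1.15, adjusted p = 3.4e-21, adjusted p = 0.16 with an estimated correlation), and 7 with size factors. Organizer genes had 0 of 40 higher and 1 lower (median -0.04, adjusted p = 0.95). The count was 2 without LiCl 2, 1 without control 4 and 6 without control 5, 3 with no batch term, 7 with no filter and 672 with the libraries of this comparison alone.

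Sia at stage 9 gave 52 genes, 49 of them higher. Xelaev18019203m had 614 and 606 RPKM against 15.9 and 10.1 in controls (5.53 ± 0.24, adjusted p = 8.4e-07, n = 2). The globin row hbg1.L had 46.3 ± 1.36 with 0 reads in controls, at least 315-fold higher than a floor of 3 reads per library, which covers counting error only. The neural gene irx2.L (1.71 ± 0.18, adjusted p = 0.00087) and tbx2.L (2.83 ± 0.27, adjusted p = 0.00049) rose. Organizer genes had 4 of 40 higher (21 higher and 2 lower adjusted over the list alone, median 0.63, adjusted p = 5.8e-24) and neural plate genes 4 of 32 (14 higher and 3 lower adjusted over the list alone, median 0.26, adjusted p = 3.3e-16), with adjusted p = 0.077 for each with an estimated correlation. Among early β-catenin targets 1 of 17 was higher, with a median of -0.08, a mean of 0.28 and a test pointing down (adjusted p = 0.98). That 1 is Xelaev18019203m, the row of the supplied mRNA. Without it limma called 0 of 16 (2 higher and 1 lower adjusted over the list alone), with a median of -0.11 and a mean of -0.05 (adjusted p = 0.15). The count was 28 without Sia 1, 34 without control 4 and 25 without control 5, 21 with no batch term, 114 with no filter and 5 with the libraries of this comparison alone.

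In the libraries labelled Wnt8 at stage 9, wnt8a was not called (wnt8a.L 21.2, 12.7 and 23.6 RPKM against 27.0, 6.81 and 26.0 in controls, 0.13 ± 0.23, adjusted p = 0.88, n = 3). The row wnt8a.S had 8.23, 0.694 and 10.3 against 13.1, 1.52 and 13.6, below its control in 3 of 3 batches (-0.59 ± 0.30, adjusted p = 0.59). Siamois row Xelaev18019203m went from 12.1 ± 2.82 to 43.9 ± 15.4 (1.77 ± 0.20, adjusted p = 0.0096) and hoxd1.L by 1.97 ± 0.22 (adjusted p = 0.0096). Early β-catenin targets had 6 of 17 higher (14 adjusted over the list alone, median 0.78, adjusted p = 2.5e-26). Zygotic Wnt targets had 6 of 32 higher (17 higher and 1 lower adjusted over the list alone, median 0.59, adjusted p = 2e-14), with adjusted p = 0.046 with an estimated correlation and 0.06 under the earlier matching. Ribosomal protein genes shifted up as a set (median 0.29, adjusted p = 4.6e-38, adjusted p = 0.2 with an estimated correlation) with 0 of 143 called (5 higher adjusted over the list alone). Reference genes (median 0.13, adjusted p = 1.4e-05) and heat shock genes (median 0.13, adjusted p = 4.5e-05) shifted up too, with 0 of 33 and 0 of 24 called and adjusted p = 0.2 for each with an estimated correlation. The 20 genes called, 19 of them higher, depend on single libraries. None (0) were called without Wnt8 3 or without control 2, 6 without Wnt8 2, 5 without control 3 and 37 without Wnt8 1. With no filter limma called 0, with no batch term 2, and with the libraries of this comparison alone 2. In the fit with the filter and all libraries, 1574 genes had an unadjusted p under 0.05, and voom on the recovered reads, added after seeing the data, called 47.

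Cer at stage 9 gave 74 genes, 35 higher and 39 lower. Cer1.S had 5350, 4870 and 6620 RPKM against 8.60, 3.86 and 10.6 in controls (9.52 ± 0.29, adjusted p = 3.1e-08, n = 3). The Nodal antagonist lefty.S fell from 11.9 ± 6.48 to 0.392 ± 0.118 (-3.64 ± 0.33, adjusted p = 0.0017), and olig4.S, a neural transcription factor gene, rose (1.91 ± 0.20, adjusted p = 0.0023). Nodal pathway genes had 16 of 47 lower (31 adjusted over the list alone, median -0.85, adjusted p = 7.4e-50), and under the earlier matching 16 of 57 lower and 3 higher. Ventral BMP genes had 8 of 25 lower (12 lower and 2 higher adjusted over the list alone, median -0.33, adjusted p = 3.1e-12) and mesoderm genes 6 of 29 (10 lower and 1 higher adjusted over the list alone, median -0.21, adjusted p = 1.1e-07). Neural plate genes had 4 of 32 higher (14 higher and 1 lower adjusted over the list alone, median 0.31, adjusted p = 2.9e-15). Zygotic Wnt targets, lower as a set at stage 10.5, shifted up (median 0.47, adjusted p = 6.3e-09) with 0 of 32 called (8 higher adjusted over the list alone). With an estimated correlation each of these 5 lists had adjusted p = 0.068. Endoderm genes had 6 of 20 lower and 1 higher (11 and 2 adjusted over the list alone, median -0.69, adjusted p = 5.4e-10, adjusted p = 0.13 with an estimated correlation). The count was 30 without Cer 1, 10 without Cer 3, 20 without control 1, 49 without control 2 and 10 without control 3, 8 with no batch term, 16 with no filter, 14 with the libraries of this comparison alone and 137 with voom.

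LiCl against Sia at stage 9 gave 124 genes, 23 higher and 101 lower in LiCl. The siamois copy Xelaev18000884m (3.21 ± 0.21, adjusted p = 2.7e-05, n = 2 per group) and myf5.S (1.64 ± 0.18, adjusted p = 8e-04) were higher in LiCl, and tbx2.L (-2.74 ± 0.27, adjusted p = 0.00054) was higher in Sia. Organizer genes had 6 of 40 lower in LiCl (20 lower and 2 higher adjusted over the list alone, median -0.63, adjusted p = 6e-18, adjusted p = 0.15 with an estimated correlation). Neural plate genes had 8 of 32 lower (15 lower and 1 higher adjusted over the list alone, median -0.45, adjusted p = 2.7e-19, adjusted p = 0.12 with an estimated correlation). The count was 274 without Sia 1, 49 without LiCl 2 and 40 without Sia 2, 13 with no batch term and 61 with the libraries of this comparison alone.

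**Figure D4:**
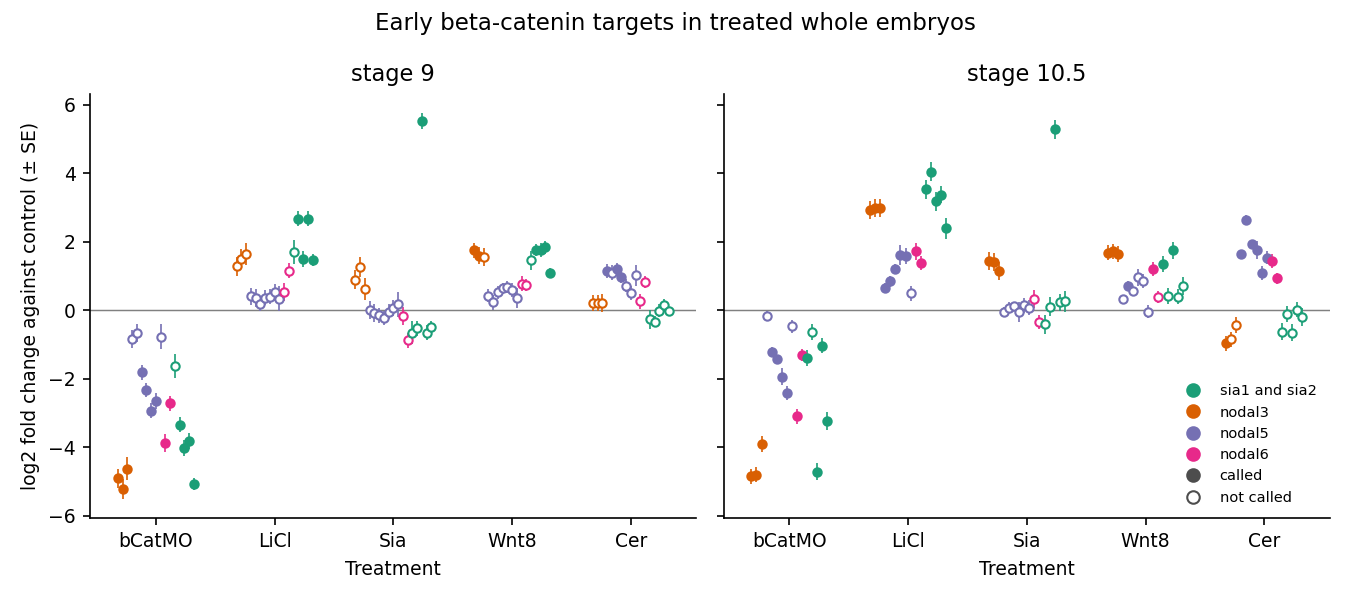
Log2 fold changes against controls with standard errors (vertical axis) of early β-catenin target genes at stage 9 and stage 10.5, 1 point per gene and treatment. The siamois copy Xelaev18019204m lay at -3.82 at stage 9 and -1.03 at stage 10.5 in bCatMO, and at 2.68 and 3.38 in LiCl. On this scale a fall is limited by the level in controls.

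Whether an effect differed between the stages was tested over 546 listed genes. With bCatMO, 30 genes differed, 12 with a higher log2 fold change at stage 10.5 and 18 with a lower one. The examples named here were chosen after their values were seen. Siamois copy Xelaev18019204m had -3.82 at stage 9 and -1.03 at stage 10.5 (difference 2.80 ± 0.32, adjusted p = 4.5e-06). In the other direction, Otx2 (Xelaev18041108m) had -0.86 and -3.82 (-2.97 ± 0.36, adjusted p = 6.9e-06) and hhex.S -0.11 and -2.83 (-2.72 ± 0.32, adjusted p = 6.9e-06). With LiCl 85 genes differed (58 higher at stage 10.5, 27 lower), such as the neural gene sox2.1 at -0.74 and 1.09 (1.84 ± 0.26, adjusted p = 0.00024). With Sia 24 differed (3 and 21), such as klf5.S at 0.13 and -1.14 (-1.27 ± 0.14, adjusted p = 2.7e-06). In the libraries labelled Wnt8 47 genes differed (4 and 43), among them msx1.S, a BMP target, at 0.95 and -2.42 (-3.37 ± 0.44, adjusted p = 4e-05) and the Wnt receptor gene fzd10.L at 1.49 and -0.45 (-1.94 ± 0.23, adjusted p = 3.6e-05). With Cer 99 differed (21 and 78), among them hhex.S at -0.27 and -3.66 (-3.39 ± 0.28, adjusted p = 1.2e-08) and irx3.L at 0.11 and -3.46 (-3.58 ± 0.31, adjusted p = 1.2e-08). No gene was called in opposite directions at the 2 stages (0 in each treatment). The stages were normalised in separate tables, so fold changes and not levels were compared. On the log2(RPKM + 0.5) scale a fall is limited by the level in controls. A gene that is low in controls at 1 stage can thus differ between stages for that reason alone, which was not tested.

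Several of these counts rested on single libraries. For bCatMO the count was 18 without bCatMO 2 of stage 10.5, 13 without bCatMO 1 of stage 9 and 12 without control 4 of stage 9. For LiCl it was 27 without LiCl 1 and 54 without control 3 of stage 10.5, and 8 without LiCl 2, 39 without control 4 and 47 without control 5 of stage 9. For Sia it was 3 without Sia 1, 8 without control 2 and 13 without control 3 of stage 10.5, and 39 without Sia 1, 12 without Sia 2 and 10 without control 5 of stage 9. For the libraries labelled Wnt8 it was 90 without control 1 of stage 9. With no batch term the counts were 10 for bCatMO, 16 for LiCl, 0 for Sia, 5 for the libraries labelled Wnt8 and 32 for Cer, all from limma fits. For Sia, limma's voom on the recovered reads with the batch term, chosen after seeing the data, gave 23.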

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

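Of the tests below, the test of whether other globin genes rose, and the counts by how many pairs or stages a split keeps, were chosen after the result was seen, as was the matching of list names at stage 9.

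In 12 of 86 groups of 4 to 10 libraries, 1 library stood far from the others, where chance flags about 1 in 20 groups, or 4.3 here. Dorsal half-embryo 1 accounts for 5 of them, all high. It had 145 RPKM of chordin Xelaev18027421m (others 60.5 to 79.8), 152 of chordin Xelaev18027420m (72.7 to 95), 182 of Xelaev18029538m (71.3 to 90.6), 303 of cer1.S (88.2 to 150) and 56.6 of Otx2 Xelaev18041108m (32.8 to 38.1). Ventral half-embryo 3 had 2.40 RPKM of Xelaev18027421m (others 0.235 to 0.758) and 3.21 of Xelaev18027420m (0.134 to 1). Ventral half-embryo 1 had 305 RPKM of bambi.L (others 96.6 to 150), and dorsal half-embryo 3 had 48.2 of nodal3 Xelaev18018867m (24 to 29.7). Ventral half-embryo 4 was low in the KLF2 match Xelaev18006666m, at 23.5 RPKM (others 28.4 to 30.4). Control 6 of stage 10.5 had 28.9 RPKM of cer1.L (others 8.63 to 14.9), and control 5 of stage 9 had 20.4 of Xelaev18018867m (30.9 to 34.6).

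Effects differed between the stages, by the test of the difference, for 30 listed genes with bCatMO, 85 with LiCl, 24 with Sia, 47 in the libraries labelled Wnt8 and 99 with Cer. For the libraries labelled Wnt8, 5 of 100 splits of the libraries gave as many genes, the real one included, and the highest other gave 128. For Cer it was 6 of 100 splits, with a highest other of 188, so that chance is not excluded by these counts alone. The other splits with as many genes (4 and 5) all kept the real grouping at 1 stage, as 18 splits did, so they still hold a treatment effect. The 81 splits that kept it at neither stage gave at most 9 and 69.

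For the half-embryos 2 of 100 splits gave as many genes as the real 125, a share under 0.05 that excludes chance only if the pairing of the libraries is set aside. The other one, with 149, set dorsal 2, 4 and 5 and ventral 2 and 5 against the rest. It parts 1 pair, as 22 splits do, whereas the real split parts all 5, and so it follows a difference between pairs. Of the 14 splits that part all 5 pairs, the highest other gave 0 genes by limma (as did the 64 splits that part 3), but 14 are too few for a share under 0.05. With the pair as a block the real count was 422.

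For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, and the real split was the 1 with the largest result each time. For bCatMO at stage 10.5 it gave 1346 genes and the highest other 8, and for the dorsal set a median of -1.42 and 1.08. For the libraries labelled Wnt8 it gave 87 and 1 genes at stage 10.5, dorsal medians of 0.65 and -0.57, and 20 and 1 genes at stage 9. For Cer it gave 856 and 0 genes at stage 10.5, dorsal medians of -0.79 and 0.68, and 74 and 0 genes at stage 9.

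At both stages the same 26 genes were called higher in bCatMO, with medians of 0.85 ± 0.13 (stage 10.5) and 0.86 ± 0.14 (stage 9, SE of the median), pbk.L, zfand2a.L, hdac2.S and plk1.L among them. If they rose because the dorsal axis signal was lost, they would lie lower in dorsal half-embryos or fall in LiCl, by a median of -0.5 or below. Their medians were 0.04 ± 0.02 between the half-embryos, where 0 were called, and -0.22 ± 0.06 in LiCl, both above -0.5. These errors come from resampled genes, not embryos. The half-embryo values argue against that loss as the whole cause. In LiCl 8 of the 26 were called lower and 0 higher, beside 1953 of all 18834 genes called lower. LiCl shares control libraries with the fit that chose the 26, so its values cannot decide this. An effect of the morpholino on messages other than ctnnb1 may explain the 26 genes, but every bCatMO library got the same oligonucleotide and the design holds no control oligonucleotide. An effect of β-catenin outside the dorsal axis also stays open and was not tested.

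At stage 10.5, 282 genes were lower in both bCatMO and LiCl, although these treatments move β-catenin in opposite directions. As given above, the count was 5 with no batch term (0.5 from independent lists) and 0 by limma at 2-fold or more (0.3). It was 53 with each comparison's own libraries (31.5) and as low as 54 without 1 library (control 3, 17.2). With size factors 205 were lower in both (62.1), which argues against scaling by a few abundant genes as the whole cause. With separate control libraries 0 were, but the lists were then short, with 31 and 181 genes in 1 way of splitting the controls (0.3 expected) and 251 and 0 in the other (0 expected). Those fits also had no batch term, and each way set 1 treatment against controls of other batches. Unchanged groups simulated against the same controls shared 0 genes on average (real effects left out) and independent lists would share 101 (shared controls left out), so how much of the 282 comes from the shared controls cannot be told apart from an effect common to both treatments, which was not tested.

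The globin gene hbg1.L had 45.3 to 53.1 RPKM in the 4 Sia libraries and at most 0.431 in any other. The highest other globin row reached 1.1 times hbg1.L in a Sia library, but that bound was a wrong test because the same rows reach 87 (Xelaev18045095m) and 81.2 RPKM (hbz.L) in libraries of other groups at stage 10.5. Blood cells or other globin-expressing RNA would raise the other globin rows, yet limma called 0 of the 6 tested ones higher at either stage, with log2 fold changes from -0.14 to 0.23. The ratio of hbg1.L to the siamois row was 0.0805, 0.0758, 0.0769 and 0.0748, a highest over lowest of 1.08. A candidate explanation is therefore that the injected siamois mRNA carried globin sequence, such as an untranslated region, which is a hypothesis tested on the data it was found in.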

How the results depend on the processing

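Tests chosen after the result was seen were voom on the recovered reads, leaving out batch 4 or pair 4, and the replicate block with voom. So were early β-catenin targets without the siamois row and the stage 9 matching of list names. The results below are counts of genes called unless said otherwise. Most values of named genes kept their direction and their side of the threshold under the other settings, but 377 values lost their call when 1 library was left out, 140 with no batch term, 76 with a fold minimum, 63 with no filter, 44 with the comparison's own libraries, 30 with homeologs summed, 8 and 3 with pseudocounts of 0.1 and 1, 5 with size factors, 12 with voom, 5 without pair 4 and 4 without batch 4. The fold minimum removes calls by its construction and the left-out library by having fewer samples. For the other settings the cause was not tested.

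Counts of genes called in a comparison stayed within 1.5 times of the reported ones with pseudocounts of 0.1 and 1 and with size factors. With no filter, stage 10.5 gave 842 (bCatMO), 1237 (Sia) and 39 (Wnt8), and stage 9 gave 84 (bCatMO), 7 (LiCl), 114 (Sia), 0 (Wnt8, by limma, against 1574 at an unadjusted p under 0.05 with the filter) and 16 (Cer). The overlap of genes lower in bCatMO and higher in LiCl was then 67. With homeologs summed Wnt8 at stage 10.5 gave 57. The cause was not tested.

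Without the batch term (no replicate block) stage 10.5 gave 166 (bCatMO), 146 (LiCl), 263 (Sia), 8 (Wnt8), 335 (Cer) and 152 (LiCl against Sia). Stage 9 gave 51, 3, 21, 2, 8 and 13 in the same order. Differences between stages were 10 (bCatMO), 16 (LiCl), 0 (Sia), 5 (Wnt8) and 32 (Cer), and the overlap was 29. For the half-embryos the pair as a block gave 422 in place of 125, and 561 with voom. The block ended the calls of 4 lists with an estimated correlation (epidermis, germ plasm, Nodal and ventral BMP). It changed no other call of a named gene or list between the half-embryos, though it raised the number of list members called.

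With the libraries of a comparison alone stage 10.5 gave 323 (bCatMO), 131 (Wnt8) and 615 (LiCl against Sia). Stage 9 gave 407 (bCatMO), 672 (LiCl), 5 (Sia), 2 (Wnt8), 14 (Cer) and 61 (LiCl against Sia). Differences between stages were 78 (bCatMO), 215 (LiCl) and 42 (Sia). The cause was not tested.

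With a log2 fold change of at least 1 required, stage 10.5 gave 131 (bCatMO), 204 (LiCl), 348 (Sia), 48 (Wnt8), 379 (Cer) and 296 (LiCl against Sia), and stage 9 gave 63 (bCatMO) and 48 (Cer). Differences between stages were 18 (bCatMO), 43 (LiCl) and 63 (Cer), and the overlap was 44. Each falls by construction. Voom on the recovered reads gave 47 (Wnt8) and 137 (Cer) at stage 9, and the half-embryos gave 70 without pair 4. Without batch 4 Wnt8 gave 61 and Cer 681 at stage 10.5. The list tests passing fell from 124 to 30 with an estimated correlation, and were 117 of 228 with each table's own descriptions.

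Leaving out 1 library at a time gave, at stage 10.5, 490 to 1625 (bCatMO), 595 to 1565 (LiCl), 306 to 556 (Sia), 23 to 78 (Wnt8), 562 to 771 (Cer), 339 to 1112 (LiCl against Sia) and 90 to 123 (half-embryos). At stage 9 it gave 50 to 74 (bCatMO), 1 to 81 (LiCl), 25 to 69 (Sia), 0 to 37 (Wnt8), 10 to 98 (Cer) and 40 to 274 (LiCl against Sia). Differences between stages were 12 to 38 (bCatMO), 8 to 94 (LiCl), 3 to 39 (Sia), 42 to 90 (Wnt8) and 84 to 98 (Cer), and the overlap was 43 to 127. The dorsal set's median ranged from -1.6 to -1.21 (bCatMO), 0.67 to 0.89 (LiCl), 0.73 to 1.06 (Sia), 0.62 to 0.77 (Wnt8) and -0.92 to -0.72 (Cer). For bCatMO it was -2.37 with voom and -2.1 with a pseudocount of 0.1. The libraries behind these ranges are named in the report where a count moved by over 1.5 times. The balance of directions turned for LiCl at stage 9 (18 of 83 higher, but 5 of 7 with no filter and 3 of 3 with no batch term), and with the comparison's own libraries for Wnt8 at stage 10.5 (72 of 131 higher) and Cer at stage 9 (35 of 74 higher, but 13 of 14). Cer at stage 9 also turned with a pseudocount of 1 (46 of 84), no filter (9 of 16) and homeologs summed (31 of 60), and Wnt8 at stage 10.5 had 4 of 8 higher with no batch term. The share higher moved by over 10 points without turning for bCatMO at stage 10.5 (27.6%, but 16.9% with no batch term and 16% with the fold minimum) and stage 9 (26.4%, 13.7% with no batch term, 36.6% with its own libraries), Sia (56.1%, 75.8% with no filter, 81.7% with no batch term, 78.2% with the fold minimum), Wnt8 (42.5%, 27.1% with the fold minimum) and Cer (36.2%, 23.7%) at stage 10.5, Cer at stage 9 (47.3%, 29.3% with a pseudocount of 0.1, 25% with no batch term, 33.3% with the fold minimum), LiCl against Sia (25.2%, 35.3% with its own libraries) and the half-embryos (80.8%, 67.7% with block and voom).

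Of the reported genes, those kept in every such fit at stage 10.5 were 388 of 1346 (bCatMO), 366 of 2668 (LiCl), 159 of 784 (Sia), 16 of 87 (Wnt8), 500 of 856 (Cer), 156 of 1101 (LiCl against Sia) and 85 of 125 (half-embryos). At stage 9 they were 42 of 129, 1 of 83, 13 of 52, 0 of 20, 8 of 74 and 32 of 124 in the same order of treatments, and 0 called genes changed sign.

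Signs reversed in 11 cases, and apart from otx1.S and cer1.L the genes were not called. Ctnnb1 row Xelaev18033202m in bCatMO at stage 9 went to 0.02 with no batch term, to 0 without bCatMO 1 and to 0.01 without control 4, and leaving out 1 library gave -0.03 to 0.01. For wnt8a.L in Wnt8 at stage 9 the value was 0 with homeologs summed, -0.10 without Wnt8 2 and -0.19 without control 2, in a leave-one-out range up to 0.43. In Sia at stage 10.5, Xelaev18000884m went to -0.05 without Sia 1 and -0.02 without control 2 (range up to 0.50), Xelaev18019204m to -0.09 without Sia 2 (range up to 0.54), and the called otx1.S (0.78) to -0.13 with homeologs summed. The called fall of cer1.L in Cer at stage 10.5 became 5.69 with homeologs summed, since the sum holds cer1.S.

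With size factors 4 list calls changed, and members called fell from 21 to 12 (ribosomal protein, LiCl against Sia) and from 4 to 2 (ribosomal protein, bCatMO) and rose from 4 to 7 (early targets, LiCl at stage 9). Endoderm lost its call in LiCl (adjusted p = 0.0076 to 0.093) and in Sia (0.035 to 0.14) at stage 10.5, and zygotic Wnt targets gained one in Sia at stage 10.5 (0.057 to 0.02) and stage 9 (0.055 to 0.038). List medians changed sign for heat shock and for p53 in LiCl at stage 10.5 (-0.04 to 0.03 each), for organizer genes in LiCl against Sia at stage 10.5 (-0.01 to 0.02), for antagonists in LiCl (-0.01 to 0.01) and for mesoderm in LiCl against Sia (-0.01 to 0.01) at stage 9. A list's median, mean and test differed in sign only for lists that did not pass the test with the preset correlation, such as early β-catenin targets in Sia at stage 9 (-0.08, 0.28 and down) and ciliated cell genes in LiCl against Sia at stage 10.5 (0.41, -0.05 and up).

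Depth limits the low values. At stage 10.5 a floor of 3 reads was 0.155 RPKM of hbg1.L per library, and changes below such a floor were not detectable. The RPKM of different libraries were otherwise set side by side as the authors scaled them.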

Other observations

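No test in this part was chosen after the result was seen, except for the matching of list names at stage 9, and the values are given without an explanation. Some genes outside the organizer rose with Sia at stage 10.5. The PHYHD1 match LOC100490918-like.L had 42.8 ± 18.1 RPKM against 0.0436 ± 0.0277 in controls (adjusted p = 3.8e-09 by limma, n = 2), and the RPRML match Xelaev18043374m had 42.4 ± 31.5 against 0.0122 ± 0.0172 (adjusted p = 8.4e-08). In LiCl these rows averaged 0.146 ± 0.0516 and 0.0132 ± 0.0186. The neuronal STMN2 match Xelaev18032124m had 7.93 ± 7.80 RPKM against 0.0212 ± 0.0117 (adjusted p = 7.6e-05). The epidermis and mesoderm lists had falling medians in Sia (adjusted p = 0.35 for each with an estimated correlation), with 3 and 4 members called higher. The GATA3 match Xelaev18017847m rose (2.03 ± 0.18 on the log2 scale, adjusted p = 2.1e-05, 2 of 2 batches), as did foxf1.L (2.05 ± 0.17, adjusted p = 1.4e-05, 2 of 2 batches). At stage 9 gmnc-like.L rose with Sia from 0.177 ± 0.0369 to 7.39 ± 3.59 RPKM (3.47 ± 0.27, adjusted p = 0.00016).

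With Cer at stage 10.5 the OSR1 match Xetrov90028455m.L fell from 10.8 ± 3.93 to 0.207 ± 0.288 RPKM (-4.02 ± 0.14, adjusted p = 3e-08, n = 3). The same GATA3 row, Xelaev18017847m, fell (-2.83 ± 0.16, adjusted p = 5.6e-07), and so did the Notch ligand gene dll1.S (-1.26 ± 0.16, adjusted p = 0.00026) and the kinase gene plk3.L (-1.52 ± 0.08, adjusted p = 4.3e-07), each in 3 of 3 batches. In the same libraries otx1.L rose (1.1 ± 0.16, adjusted p = 0.00091, 3 of 3 batches). With LiCl the cilia regulator foxj1.S rose (1.05 ± 0.14, adjusted p = 0.00096) and the GAPDH match Xelaev18034420m fell (-0.78 ± 0.11, adjusted p = 0.0013), each in 2 of 2 batches.

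Ribosomal protein genes shifted up as a set with Cer at stage 9 (median 0.19, adjusted p = 2e-30, and 0.21 with an estimated correlation, beside reference genes with a median of 0.07, adjusted p = 2e-05, and 0.2 with an estimated correlation) and with Sia and Cer at stage 10.5 (medians 0.10 and 0.09, adjusted p = 0.65 and 0.55 with an estimated correlation), with 0 members called by limma in each. Reference genes shifted up with Cer at stage 10.5 (1 of 33 called higher, 5 adjusted over the list alone, median 0.13, adjusted p = 3.2e-05, and 0.12 with an estimated correlation).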
